A study of Mus musculus with 2 samples.

How the data were processed

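The measurements come from 2 Affymetrix expression arrays of mouse cerebral cortex collected around birth, 1 array per group. The sample titles give the tissue only as brain. Per the labels' protocols, each array was hybridised with RNA pooled from 3 animals, extracted with Trizol, and biotin-labelled cRNA was made from 6 ug of total RNA. Per the labels, the control pool carried Mrtfa null alleles and floxed Mrtfb alleles without Cre, and the double knockout pool the same alleles together with a GFAP-Cre transgene. Cre is the recombinase that removes floxed segments, here under a GFAP promoter by the transgene's name. The labels give postnatal day 0 for both pools, apart from the description of the double knockout sample, which gives postnatal day 1.

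The deposited values are probe set intensity signals on a linear scale, computed by the authors with MAS5, per the submitters' processing notes. The version, the target scaling and any further step are not given in the sources used here. Each of the 45101 probe sets has 1 signal per array, printed to 1 decimal. The 2% trimmed mean of all signals was 500.002 on both arrays, and the signals ran from 0.1 to 15987.5 in the control pool and to 15263.9 in the double knockout pool. The number of columns belonging to no listed sample was 0.

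Probe sets were named from a table pairing the array's probe sets with platform annotation, and the Entrez identifiers were matched to a RefSeq gene table of mouse assembly GRCm38.p6, used for names and for the order of neighbouring genes only. Of the 45037 probe sets left after setting aside 64 control probe sets, 34945 named 1 gene, 932 named several genes and 9160 had no gene name. Entrez identifiers of 99.4% of the probe sets naming 1 gene were matched, and 0 symbols needed updating. Probe sets with several genes or none entered no gene-level value.

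Values were computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6, and plotted with matplotlib 3.10.9. Signals were first centred so that the median log2 difference over probe sets bright on both arrays was 0, which took a shift of 0.0037 log2. Signals under a floor of 178.6, the 50th percentile of all non-control signals of both arrays, were then set to the floor. A gene was measured when its probe set reached the floor on at least 1 array, and its value came from the probe set with the highest mean log2 signal. All differences are the double knockout pool minus the control pool on the log2 scale. Where only 1 array reached the floor, the fold is a lower bound, written as at least N-fold. The threshold for counting genes was 2-fold.

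With 1 array per group there is no replicate, so no test was made and no p-value is given. Pooling averages the 3 animals of a group and hides how they differ. The SD printed beside a gene is taken over its own probe sets at or above the floor on both arrays. It covers spread between those probe sets, which may read different transcripts, and none between animals. Pooled over the 4858 genes with at least 2 such probe sets, that SD was 0.181 log2, and it was 0.203 over the 1620 dimmest of these genes and 0.155 over the 1619 brightest.

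For gene groups, 35 lists with 711 entries were written before the data were examined. They cover the targeted genes, MRTF-SRF targets, immediate early genes, actin regulators, Cdk5 and PCTAIRE kinases, migration, guidance, matrix, progenitor, neuron, glia, vascular, meningeal and neighbouring-region markers, blood, muscle and skin, sex-linked genes, and stress responses. Of these entries 527 were measured. The result of 1 list is not reported here. For each list the median difference was placed among 10000 random lists of the same size, each member drawn from 200 genes of similar mean signal. A median at or below the 2.5 percentile or at or above the 97.5 percentile was called outside the random range. By chance 1.75 of the 35 lists would lie outside if the genes of a list varied independently. Genes of a list can vary together, so more lists may lie outside by chance. The percentile describes these 2 arrays and not the conditions.

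The genes named in the text were fixed by a rule before the data were examined. It takes Mrtfb, Mrtfa, Myocd and Srf. It takes the 10 genes per direction with the largest difference among those at or above the floor on both arrays whose other probe sets at or above the floor differ the same way, leaving out unnamed transcripts, Xist and Y-linked genes. It takes the 5 largest bounds per direction, and up to 4 members of each list with the largest absolute difference among those at or above the floor on both arrays. A gene named outside this rule is said to have been chosen after its values were seen.

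Alternatives planned before the data were examined were signals without centring, trimmed-mean scaling, quantile normalization, loess centring with a span of 0.3, a floor at the 25th or 75th percentile, a pseudocount equal to the floor, no floor and no filter, the mean over a gene's probe sets, and leaving out probe sets whose suffix marks possible cross-hybridisation. Counts were also taken at 1.5-fold and 3-fold and with at least 2 probe sets past the threshold.

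The procedure was tested on simulated data for the comparison of the double knockout pool with the control pool, with 11498 genes in the step and a noise SD of 0.1985 log2 on the difference. Of 50 genes changed at each size, the 2-fold count took 2.0% of those changed 1.5-fold, 42.0% at 2-fold, 94.0% at 3-fold and 100.0% at 4-fold. Of 11298 unchanged genes, 0 were counted. The simulated noise was normal, with the same SD at every brightness, taken from the observed differences. A count of 0 under that noise does not show that the genes counted in the real data exceed noise. A simulated shift of 0.3 log2 between the arrays was recovered as 0.2952.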

Results

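Gene expression in the cerebral cortex of newborn mice was compared between 2 pools of RNA. MRTF-A and MRTF-B are coactivators of the transcription factor SRF that respond to the state of the actin cytoskeleton. Both pools are labelled null for Mrtfa, and the pool labelled double knockout also carried GFAP-Cre to delete floxed Mrtfb. As labelled, the comparison asks what deletion of Mrtfb together with the Cre transgene adds on an Mrtfa-null background. The Mrtfa signal itself nevertheless differed between the pools. Each pool held RNA of 3 animals and was read on 1 array, so the differences have no replicate check. Of 18193 named genes 11629 were measured, 11014 of them at or above the floor on both arrays. Across those genes the log2 signals of the arrays had a Pearson r of 0.990, with genes not being independent replicates.

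Mrtfb was lower in the pool labelled double knockout. Its brightest probe set read 3359 in the pool labelled control and 2475 in the pool labelled double knockout, 1.36-fold lower. A dimmer probe set differed by -0.22 log2, and the mean over both was -0.33 ± 0.15 (SD, 2 probe sets). Mrtfa, which the labels give as null in both pools, read 601.6 in the pool labelled control and 261.7 in the pool labelled double knockout, 2.30-fold lower on its only probe set. The Mrtfa signal thus differed between pools labelled alike, which need not contradict the label. Whether these probe sets lie within the deleted parts of either gene is not given in the sources used here. Srf was 1.24-fold lower on its brightest probe set, with a mean of -0.28 ± 0.05 (SD, 2 probe sets). Myocd, the third member of the coactivator family, stayed under the floor on both arrays.

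**Figure D1:**
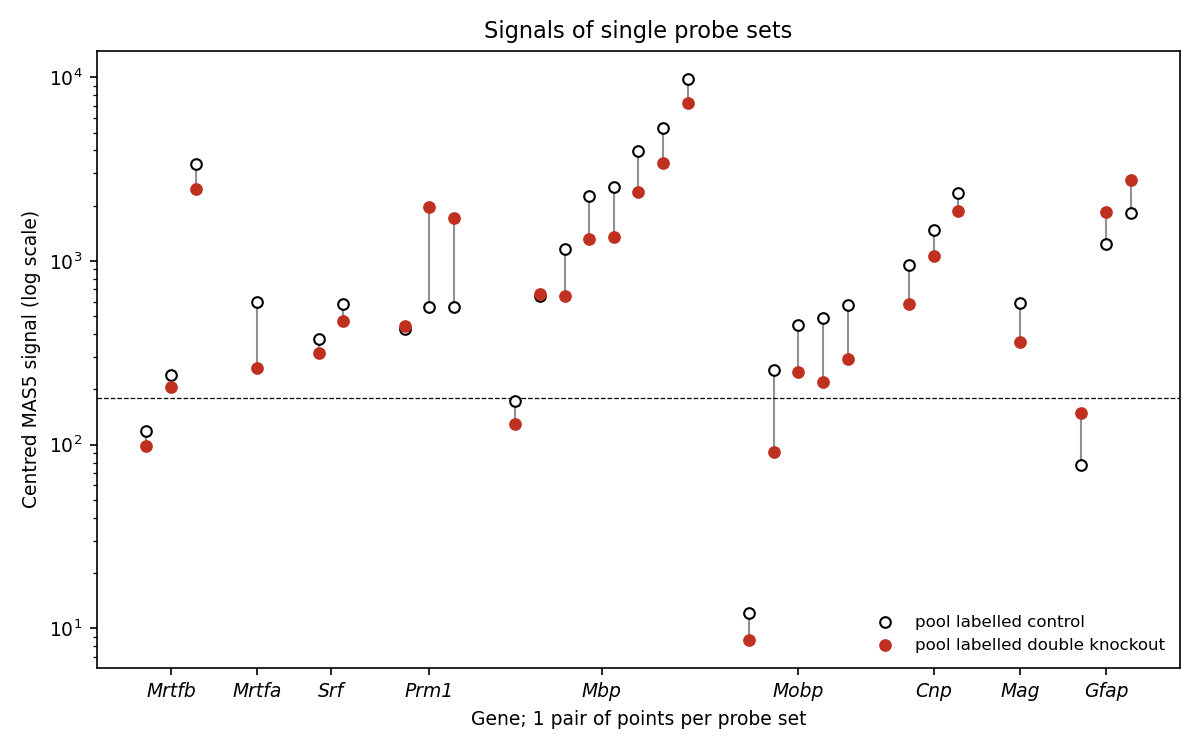
Centred MAS5 signal (log scale) of each probe set of selected genes, with an open point for the pool labelled control joined to a filled point for the pool labelled double knockout, and a dashed line at the floor of 178.6. The probe sets of Mrtfb, Mrtfa and Srf were lower in the pool labelled double knockout, both bright probe sets of Gfap were higher, and of the 3 Prm1 probe sets the lowest differed by 0.06 and the highest by 1.81 log2.

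Known MRTF-SRF targets were lower as a group in the pool labelled double knockout. Of 26 measured targets 21 were lower and 5 higher, with a median of -0.12 log2, below the medians of all 10000 random lists, whose central range was -0.05 to 0.08. No target passed 1.5-fold. Tgfb1i1, a focal adhesion protein also called Hic-5, differed by -0.45 and Mical2, an actin-oxidising enzyme, by -0.42. The muscle actins Acta1 and Acta2 differed by -0.25 and -0.24. The cytoplasmic actins Actb and Actg1, chosen after their values were seen along with Acta2, differed by -0.17 and -0.18, although the mean over the probe sets of Actb was -0.08 ± 0.12 (SD, 2 probe sets). The array's own beta-actin control probe sets averaged -0.30 ± 0.03 (SD, 3 probe sets), and the spike-in probe sets -0.09 ± 0.14 (SD, 18 probe sets). Markers of other cells and tissue differed between the same pools, with medians of -0.26 for striatum, -0.23 for oligodendrocytes and 0.21 for both meninges and microglia.

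Immediate early genes that SRF controls through its other partners, the TCF factors, did not stand apart. Their median was -0.02 over 17 genes, at the 37.6 percentile of random lists. Egr4, Junb and Ier2 differed by -0.50, -0.32 and -0.25, and Fos was higher by 0.31.

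Actin dynamics genes as a whole lay inside the random range. Of 43 measured members 22 were higher and 21 lower, with a median of 0.02 at the 42.9 percentile, or -0.01 after loess centring. Coronins went both ways, with Coro1a at 0.26, Coro1b at 0.21 and Coro1c at -0.19, and the probe sets of Coro1a differed in direction, with a mean of -0.0035 ± 0.37 (SD, 2 probe sets). Gelsolin, Gsn, which severs actin filaments, had a mean of -0.20 ± 0.08 (SD, 4 probe sets). Cofilin 1, Cfl1, chosen after its values were seen, had a mean of -0.03 ± 0.22 (SD, 2 probe sets).

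Cdk5 and PCTAIRE kinases, a list drawn up with knowledge of work on these mice and so not independent evidence, had a median of 0.04 over 5 genes at the 43.8 percentile. The Cdk5 activators Cdk5r2 and Cdk5r1 differed by -0.28 and -0.18, Cdk5 by 0.07 and Cdk17 by 0.08, although the mean over the probe sets of Cdk5 was -0.12 ± 0.28 (SD, 2 probe sets). Cdk16, chosen after its values were seen, had a mean of -0.08 ± 0.11 (SD, 3 probe sets). The list's median was -0.12 and below the random range with the mean over probe sets in place of the brightest one.

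Neuronal migration genes had a median of 0.05 over 32 genes at the 84.1 percentile. Dcx, the doublecortin of migrating neurons, was higher by 0.43, with a mean of 0.34 ± 0.14 (SD, 4 probe sets). Reln was higher by 0.29 and Slit1 differed by -0.26, and Nrp2 was higher by 0.28 on its brightest probe set but by a mean of 0.10 ± 0.16 (SD) over 3 probe sets. Axon guidance and outgrowth genes had a median of 0.04 over 35 genes at the 73.7 percentile, with Epha5 at 0.36, Plxna4 at -0.35, Efnb1 at -0.31 and Dcc at 0.23 on their brightest probe sets. The means over probe sets were smaller, at 0.15 ± 0.14 (SD, 4 probe sets) for Epha5, -0.18 ± 0.23 (SD, 2 probe sets) for Plxna4, -0.14 ± 0.16 (SD, 3 probe sets) for Efnb1 and -0.03 ± 0.36 (SD, 3 probe sets) for Dcc. Extracellular matrix and adhesion genes had a median of 0.04 over 22 genes at the 72.1 percentile, with Lama2 at 0.38, Nid1 at 0.33, Hspg2 at -0.34 and Itgb5 at -0.28, the probe sets of Itgb5 going both ways (mean -0.11 ± 0.23, SD, 3 probe sets). The matrix list came out above the random range at 0.12 (99.6 percentile) without probe sets marked for cross-hybridisation and at 0.07 with the mean over probe sets.

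Few single genes differed by 2-fold. There were 4 genes at least 2-fold higher and 5 at least 2-fold lower in the pool labelled double knockout. Of the genes at or above the floor on both arrays, 99.0% lay within 0.58 log2 in either direction, and the SD of the differences was 0.187. At 1.5-fold, 43 genes were higher and 90 lower, and this split depended on the scaling, with 66 higher and 70 lower after quantile normalization and 60 and 72 after loess centring. No gene with at least 2 probe sets at or above the floor on both arrays had all of those past 2-fold. Past 1.5-fold 1 of 4858 such genes did, Mobp.

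**Figure D2:**
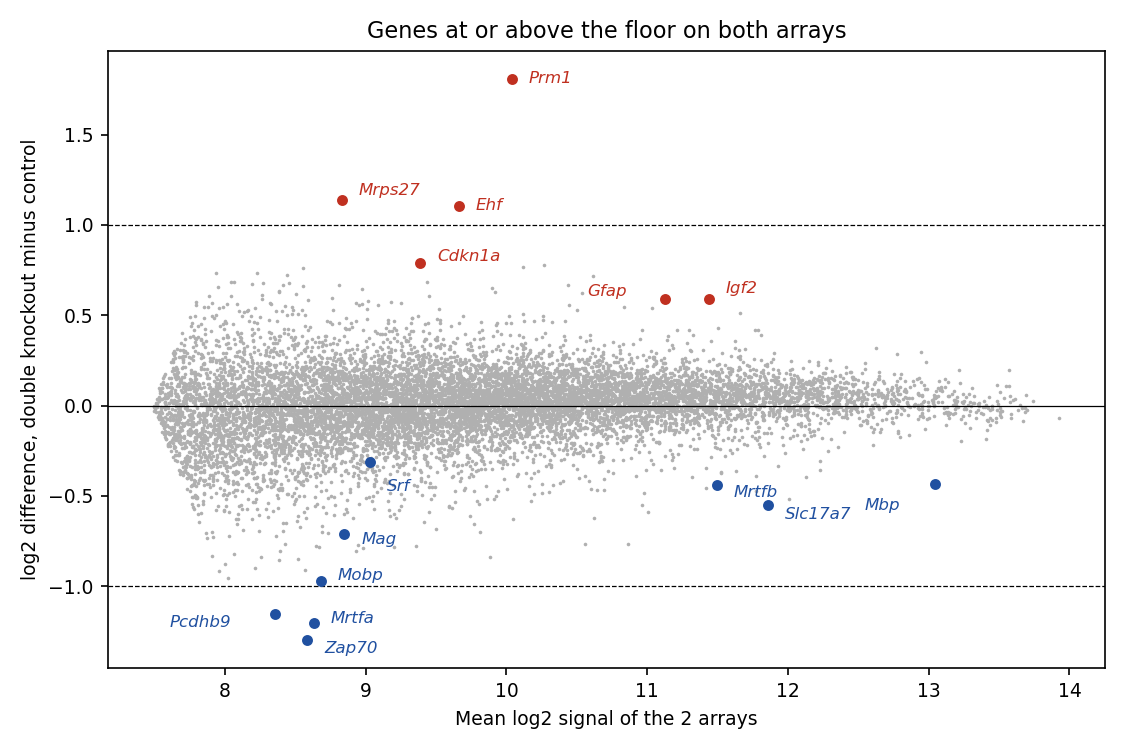
Log2 difference (pool labelled double knockout minus pool labelled control) of each gene at or above the floor on both arrays against its mean log2 signal, with selected genes named and lines at 2-fold. Most genes lie near 0, with 99.0% within 0.58 log2, and Prm1 at 1.81 is the highest point.

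The highest gene was Prm1, which encodes protamine 1, a sperm chromatin protein, at 3.50-fold (561.8 to 1968). Its 3 probe sets read 1.81, 1.60 and 0.06, a mean of 1.16 ± 0.96 (SD), and all carry the suffix for possible cross-hybridisation. Mrps27, a mitochondrial ribosomal protein, was 2.20-fold higher and Ehf, an epithelial ETS factor, 2.15-fold higher, the latter on 1 of 4 probe sets, with the same suffix. Cdkn1a, the cell cycle inhibitor p21, was 1.73-fold higher, and Pttg1, securin, had a mean of 0.62 ± 0.21 (SD, 2 probe sets). Xkr4, Tax1bp3, Tbx18, Pomc and Pde5a were higher by 0.78, 0.76, 0.74, 0.73 and 0.72. Of genes under the floor in the pool labelled control alone, Zfp691 was at least 2.05-fold higher, Spc25 at least 1.80-fold, Sstr1 and Mpeg1 each at least 1.66-fold, and Brf1 at least 1.55-fold.

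On the lower side, Zap70, a kinase of T cell receptor signalling, was 2.46-fold lower on its only probe set bright on both arrays, or -0.68 with the mean over measured probe sets. Pcdhb9, a clustered protocadherin, was 2.22-fold lower and Mobp, a myelin protein, 1.96-fold lower. The probe sets of Mobp had a mean of -0.99 ± 0.15 (SD, 3 probe sets). Adgrf5, Pigz, Gucd1, Zfp939, Hoxa9 and Mtmr14 differed by -0.96, -0.91, -0.91, -0.90, -0.87 and -0.86. Stxbp2, under the floor in the pool labelled double knockout, was at least 2.72-fold lower. Jak3 was at least 2.03-fold lower, Pglyrp1 at least 1.94-fold, and Slc35d3 and Dok2 each at least 1.72-fold. Of the 20 genes with the largest differences measured on both arrays, 17 rested on 1 probe set.

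Oligodendrocyte genes were lower in the pool labelled double knockout. Of 14 measured members 11 were lower and 3 higher, with a median of -0.23, below all 10000 random lists, or -0.11 at the 0.87 percentile with the mean over probe sets. Mag, a myelin glycoprotein, was 1.63-fold lower, and Ugt8a, which makes galactosylceramide for myelin, differed by -0.54. Mbp, myelin basic protein, was lower on 6 of its 7 probe sets at or above the floor on both arrays, with a mean of -0.61 ± 0.33 (SD). Myt1 differed by -0.42. Markers of the striatum, which lies beneath the cortex, were lower in the same pool, with a median of -0.26 over 12 genes.

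Gfap, the astrocyte filament gene after which the Cre transgene is named, was 1.51-fold higher on its brightest probe set, with a mean of 0.58 ± 0.01 (SD, 2 probe sets). The astrocyte list as a whole had a median of -0.02 over 15 genes at the 6.02 percentile, but 0.10 at the 97.9 percentile without probe sets marked for cross-hybridisation, with Gjb6 at 0.35 and both Clu and Slc1a2 at -0.20. Radial glia and progenitor genes had a median of -0.01 over 19 genes at the 18.6 percentile, with the transcription regulators Emx2, Id4, Hes5 and Sox9 at -0.45, -0.36, -0.26 and -0.20. The probe sets of Sox9 went both ways, with a mean of -0.08 ± 0.17 (SD, 2 probe sets). Intermediate progenitor genes had a median of -0.20 over 9 genes at the 0.38 percentile, with Sstr2 at -0.52, Insm1 at -0.41, Btg2 at -0.20 and Elavl4 at 0.13, the probe sets of Elavl4 having a mean of -0.01 ± 0.12 (SD, 3 probe sets). That call ended with the floor at the 75th or the 25th percentile, the highest median being -0.01. Cell cycle genes had a median of -0.10 over 22 genes at the 11.9 percentile, with Cdk1 at -0.48, Mcm2 at -0.40, Hmmr at -0.40 and Cenpf at 0.25. The cell cycle median was -0.02 after quantile normalization, and Hmmr was at 0.16 without probe sets marked for cross-hybridisation.

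Neuron subtype markers stayed inside the random range. Upper-layer genes had a median of 0.08 over 13 genes at the 91.6 percentile, with Rorb at 0.34, Inhba at -0.32 and both Pou3f2 and Cux1 at 0.17, and the median was 0.01 with the mean over probe sets. The 8 probe sets of Cux1 at or above the floor on both arrays had a mean of -0.12 ± 0.23 (SD), opposite to its brightest one. Deep-layer genes had a median of 0.08 over 18 genes at the 92.9 percentile, with Nr4a2 at 0.25, Bcl11b at 0.18, Syt6 at -0.30 and Foxp2 at -0.20, the probe sets of Bcl11b having a mean of -0.06 ± 0.26 (SD, 4 probe sets). The deep-layer list came out above the range after quantile normalization, after loess centring and with the floor at the 75th percentile, but its median was -0.0053 at the 33.1 percentile with the mean over probe sets. Interneuron genes had a median of 0.06 over 15 genes at the 82.7 percentile, with the transcription factors Dlx1, Maf and Dlx2 at 0.64, 0.38 and 0.27 and the neuropeptide Npy at -0.22, the probe sets of Maf having a mean of 0.14 ± 0.18 (SD, 5 probe sets). Synapse genes had a median of -0.03 over 26 genes at the 0.16 percentile, a small difference set against a random range of -0.01 to 0.08. The vesicular glutamate transporter Slc17a7 differed by -0.55 and the scaffold Dlg4 by -0.26, while the brightest probe sets of Nlgn3 and Gria3 were higher by 0.63 and 0.30. Over all their probe sets the means were 0.16 ± 0.49 (SD, 3 probe sets) for Nlgn3, 0.10 ± 0.29 (SD, 2 probe sets) for Gria3 and -0.07 ± 0.30 (SD, 3 probe sets) for Dlg4, with probe sets in both directions for each.

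Markers of immune cells and of tissue around the cortex differed between the pools. Microglia and macrophage genes had a median of 0.21, with 14 of 18 higher, above all 10000 random lists, and Mrc1, C1qc, C1qb and Lyz2 were higher by 0.68, 0.46, 0.37 and 0.36, with a mean of 0.21 ± 0.14 (SD) over 3 probe sets for C1qb. The 4 lower members, chosen after their values were seen, were Cd14, Cx3cr1, Fcer1g and Aif1 at -0.14, -0.13, -0.08 and -0.06. Genes of the meninges and fibroblasts had a median of 0.21, with 16 of 19 higher, also above all random lists, and Aldh1a2, Igf2, Islr and Ogn were higher by 0.68, 0.59, 0.53 and 0.51, with a mean of 0.27 ± 0.34 (SD) over 2 probe sets for Ogn. Striatal genes were lower in 11 of 12 cases, below all random lists, with the dopamine receptor Drd2 at -0.42, Six3 at -0.41, the opioid precursor Penk at -0.39 and Gpr6 at -0.35. The targeted genes and family had a median of -0.44 over 3 genes at the 0.13 percentile.

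**Figure D3:**
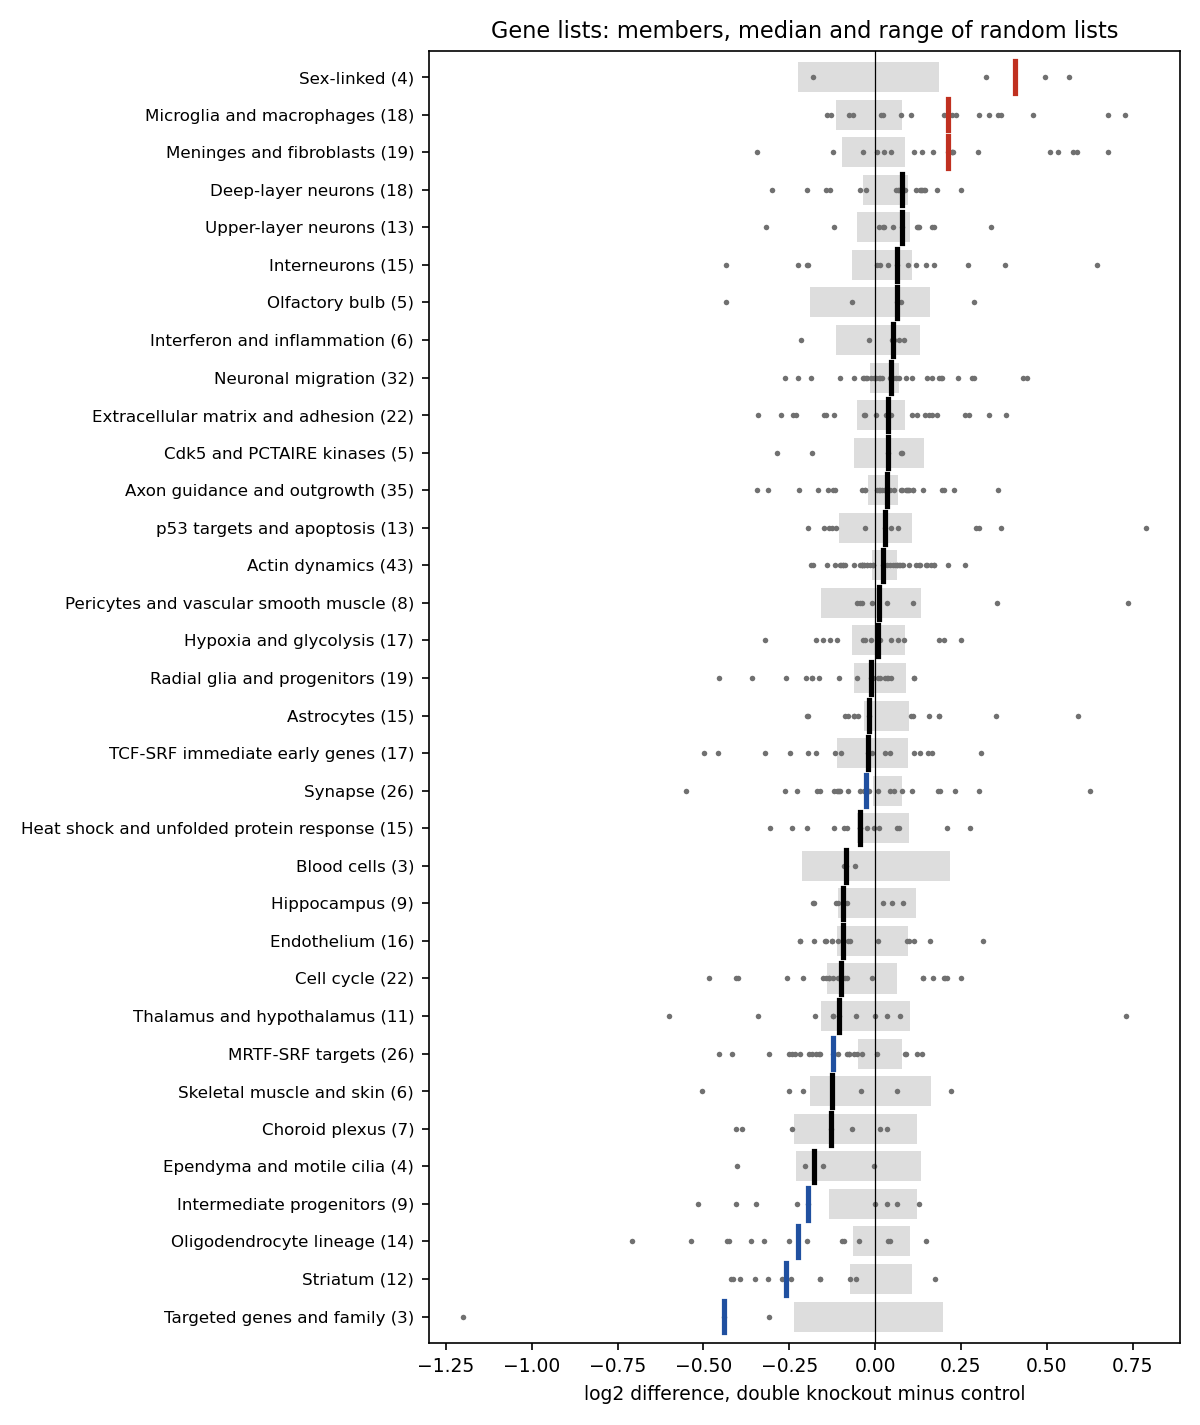
Log2 difference (pool labelled double knockout minus pool labelled control) for each gene list reported here, with a dot per measured member (their number in parentheses), a thick mark for the list median and a grey bar for the central range of the medians of 10000 random lists of similar signal. Medians below the bar are blue and above it red, with MRTF-SRF targets at -0.12, oligodendrocyte genes at -0.23 and striatal genes at -0.26 below, and microglia and meninges, both at 0.21, above.

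Other vascular, fluid-barrier and regional lists lay inside the random range. Endothelial genes had a median of -0.09 over 16 genes, with Tek at 0.31 and Slco1a4, Pecam1 and Eng at -0.22, -0.22 and -0.18. Pericyte genes had a median of 0.01 over 8 genes, with Tbx18 at 0.74 and Vtn at 0.35. Choroid plexus genes had a median of -0.13 over 7 genes, with Kcnj13 at -0.41, and ependymal genes -0.18 over 4, with Ccdc39 at -0.20. The choroid plexus gene Ttr, chosen after its values were seen, was bright in both pools, at 12405.5 in the pool labelled control and 12706.8 in the other. Thalamic and hypothalamic genes had a median of -0.10 over 11 genes, with Pomc at 0.73, Tcf7l2 at -0.60 and Hcrt at -0.34, and the median was -0.01 with the floor at the 25th percentile. Hippocampal genes had a median of -0.09 over 9 genes, with Wfs1 and Lmo2 both at -0.18. Olfactory bulb genes had a median of 0.06 over 5 genes, blood cell genes -0.09 over 3, and muscle and skin genes -0.13 over 6, with Ckm at -0.51, the last median turning to 0.06 with the floor at the 25th percentile. In total 6 lists lay below and 3 above their random ranges.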

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

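The percentiles of the gene lists were planned before the data were examined. The use of the striatum list to weigh the myelin genes, and the other tests in this part, were chosen after the results were seen.

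Probe sets without a gene name entered no comparison, and 4 of the 2670 measured ones were at least 2-fold higher in the pool labelled double knockout than in the pool labelled control. The signals of the first went from 183.5 to 388.8, 2.12-fold higher, and those of another from 220.2 to 574.9, 2.61-fold higher. Those of the other 2, under the floor in the pool labelled control, reached 413.0 and 395.5, at least 2.31-fold and at least 2.21-fold higher. In the other direction 3 unnamed probe sets were lower, the brightest by 2.81-fold (6455 to 2293) and the others by 2.25-fold and 2.11-fold.

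Myelin genes were lower in the pool labelled double knockout, with Mbp, Mag, Cnp, Ugt8a and Bcas1 (Cnp and Bcas1 chosen after their values were seen) at a median of -0.43. An age difference of 1 day, which the description of the double knockout sample would allow, would act the other way, since myelin genes increase after birth. That reading rests on the median of -0.43, which is the pattern itself, and is not a separate test. Fewer cells of the whole oligodendrocyte lineage could not be excluded: the 9 lineage and precursor genes had a median of -0.091, above the myelin genes, but Myt1 at -0.42 lay within the myelin range of -0.71 to -0.32, and without Myt1 the lowest of the other 8 was -0.25. Less striatal tissue in the pool labelled double knockout may account for the pattern. The striatum list median lay at the 0 percentile of random lists, and 0 of its 12 measured genes belong to another list. Its abundant members differed unevenly, with Penk at -0.39 and Tac1 at -0.07. Meis2 and Foxp1, which cortex also expresses, were at -0.05 and 0.17 (Tac1, Meis2 and Foxp1 chosen after their values were seen). The thalamus and hypothalamus list, also subcortical, lay inside its random range, with a median of -0.10 at the 11.7 percentile. A loss of subcortical tissue in general is therefore not shown. An effect of the Mrtfb deletion stays open as untested, and it cannot be separated from dissection with 1 pool per group.

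The Mrtfa signal was 2.30-fold lower in the pool labelled double knockout, although both pools are labelled null. A chromosome segment lowered as a whole would lower neighbouring genes too. But the lowest of 40 measured neighbours, Rangap1 (chosen after its values were seen), was at -0.27 and their median was -0.05 ± 0.15 (SD). A segment that differs in sequence but leaves the neighbouring signals alike was not tested by these values. Noise of a single probe set would be rare at this size, as 1 of 500 genes of like brightness differed as much, but it stays open because no other Mrtfa probe set was there to compare. Whether the pool labelled control held animals with intact Mrtfa cannot be told apart either, because only 1 Mrtfa probe set reached the floor and its position relative to the deletion is not given in the sources used here. If the pool labelled control did hold intact Mrtfa, the comparison would also cover Mrtfa. Even as labelled it is not one of Mrtfb deletion alone, since only the pool labelled double knockout carried GFAP-Cre. Deletion and the presence of Cre cannot be told apart.

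Prm1 was 3.50-fold higher in the pool labelled double knockout. Spermatid RNA would bring the other protamine and transition protein genes, but the 5 probe sets of Prm2, Prm3, Tnp1 and Tnp2 (chosen after the value of Prm1 was seen) reached at most 63.7 in that pool, under the floor of 178.6. The second probe set at 1.60 would argue against noise of a single probe set only if the 2 share no probes. Probe sequences were not used here, so that noise stays open. A Cre transgene that carries the 3 prime part of Prm1, as some expression constructs do, could give such a split, with the remaining probe set at 0.059, but the labels do not say what the transgene carries and probe positions are not used here. Cross-hybridisation was not tested, and all 3 probe sets carry the suffix that marks it as possible.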

How the results depend on the processing

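The alternatives were planned before the data were examined. The counts of genes at least 2-fold different changed with the floor, which also sets how many genes are measured (11629 in the report). With the floor at the 25th percentile 40 of 15341 genes were higher and 91 lower, with it at the 75th percentile 1 and 0 of 6967, and with no floor and no filter 393 and 863, a setting that changes both at once and counts dim genes too. A pseudocount in place of the floor left 0 genes lower and 3 higher, of which 1 was among the 4 in the report. Without probe sets marked for cross-hybridisation 2 genes were higher. At 1.5-fold the counts were 43 higher and 90 lower, at 3-fold 1 and 0, and with at least 2 probe sets all past 2-fold 0 and 0. All 4 higher and 5 lower genes were shared with the lists under the 25th percentile floor, no floor, no centring, trimmed-mean scaling and quantile normalization. With a lower floor or none this was largely fixed in advance, since lowering the floor cannot shrink a difference apart from the centring. Of the 5 lower genes 4 were shared after loess centring, 4 without probe sets marked for cross-hybridisation and 3 with the mean over probe sets.

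The median of the MRTF-SRF targets was -0.140 to -0.089 over 10 settings, smallest in size at -0.089 with the pseudocount in place of the floor, and stayed below the random range in all 10. No centring and trimmed-mean scaling are weak checks, since they change the differences almost only by the centring shift of 0.0037 log2. Mrtfb was -0.48 to -0.33. The targeted, synapse, oligodendrocyte, striatum, microglia and meninges lists stayed outside their ranges in all 10 settings, the sex-linked list in 9 and the intermediate progenitors in 8. Lists that came outside under some settings only were the Cdk5 and PCTAIRE kinases (2 settings, low), deep-layer neurons (3, high), matrix and adhesion genes (2, high), astrocytes (1, high), and endothelium and hippocampus (1 each, low). With the floor at the 75th percentile genes with a signal below it shrank, to -0.03 for both Mrtfa and Zap70, 0.07 for Dlx1, 0.06 for Dlx2 and -0.13 for Mcm2. Of 340 medians of the other lists under alternatives, 296 moved by less than the SD of random medians and 44 by more. Of 1493 values of named genes other than Mrtfb, 1410 moved by less than the pooled SD of 0.181 and 83 by more. No list outside its random range and no gene past 2-fold changed sign (0 of each). Among named genes with smaller differences, Coro1a, Cdk5, Dcc, Elavl4, Hmmr, Cux1, Bcl11b, Rgs5, Folr1, Fech, P4ha1 and Itgb5 changed sign, each under 1 setting. Probe sets of Cdk5r1, Sox9, Nr4a2, Maf, Slc1a2 and Xbp1 also went both ways. Beyond the lists with a change of sign given beside their values, the median of the TCF-SRF genes turned to 0.04 and that of choroid plexus to 0.01 with the floor at the 75th percentile. With the floor at the 25th percentile, radial glia turned to 0.01, astrocytes to 0.0081 and pericytes to -0.01, the last also to -0.04 with no floor and no filter and to -0.0086 with the mean over probe sets. The cause of these shifts was not tested.

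No paired analysis was possible because each group has 1 array, and no array could be left out for the same reason. Signal over background limits the dim genes, where the SD over a gene's probe sets was 0.203 against 0.155 in bright ones.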

Other observations

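Stress and immune response genes showed little difference as groups. The p53 targets and apoptosis genes had a median of 0.03 over 13 genes at the 68.3 percentile of random lists, although Cdkn1a was 1.73-fold higher and Mdm2, Perp and Trp53inp1 were higher by 0.37, 0.30 and 0.29. The probe sets of Mdm2 differed widely, with a mean of 0.10 ± 0.38 (SD, 2 probe sets). Heat shock and unfolded protein response genes had a median of -0.04 over 15 genes at the 4.78 percentile, with Sdf2l1 at -0.31, Dnajb1 at 0.28, Hspb1 at -0.24 and Xbp1 at 0.21. The means over probe sets were 0.16 ± 0.17 (SD, 2 probe sets) for Dnajb1 and 0.06 ± 0.19 (SD, 4 probe sets) for Xbp1. Hypoxia and glycolysis genes had a median of 0.01 over 17 genes at the 44.1 percentile, which turned to -0.02 after quantile normalization and after loess centring, with Pfkfb3 at -0.32 and Hk2 at 0.25. Interferon and inflammation genes had a median of 0.05 over 6 genes at the 75.9 percentile, with Ifit2 at -0.21, and the median turned to -0.18 with no floor and no filter.

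The sexes of the pooled animals are not given in the labels, and the sex-linked genes differed between the pools. The Y-linked genes Kdm5d, Uty and Eif2s3y were higher in the pool labelled double knockout by 0.57, 0.49 and 0.32, and Xist, expressed from the inactive X chromosome, differed by -0.18 ± 0.01 (SD, 2 probe sets). The list's median was 0.41 over 4 genes at the 99.99 percentile, but 0.047 at the 65.6 percentile with the floor at the 75th percentile, which lies above the signals of Kdm5d and Uty in both pools. Both pools had signal from Y-linked genes and from Xist, with Eif2s3y at 647.5 and 809.7 and Xist at 5387 and 4748.

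Gapdh 3 prime over 5 prime signal was 0.719 in the pool labelled control and 0.728 in the pool labelled double knockout, and that of beta-actin 1.41 and 1.35. The spike-in probe sets had a mean difference of -0.09 ± 0.14 (SD, 18 probe sets) and the 18S control probe sets 0.45 ± 0.13 (SD, 3 probe sets). Prm1 and the floxed gene Mrtfb lie near each other on the same chromosome, each among the 20 nearest measured genes on a side of the other. The 40 measured neighbours of Prm1 had a median of -0.01, from Mrtfb at -0.44 to Parn, chosen after its values were seen, at 0.46.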
